A study of Mus musculus with 12 samples.

How the data were processed

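Poly(A) RNA of mouse optic nerve was sequenced by the submitters in 12 libraries. Groups came from the treatment label: PBS (6 libraries, replicates 1 to 6 by their titles), carboplatin (3) and selumetinib (3). The authors deposited 1 table of raw read counts per Ensembl gene, with 1 column per library and 35275 genes, and its whole numbers sum to a different total in each column. Per the submitters' processing notes, FastQC, Trimmomatic, STAR, HTSeq and DESeq2 were used with build mm10. Their versions, the annotation release, the strand setting and any filter were not given in the sources used here. Per the labels' protocols, RNA was purified with a column kit and selected with poly-T beads. Of the gene IDs, 34490 are in GENCODE M21 (build GRCm38, equal to mm10), which gave symbols, coordinates and overlapping genes. The totals run from 21793052 to 33375754 counts per library.

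The choices named here were made before the data were examined, apart from those said to be later. Genes were kept with the filterByExpr defaults (minimum count 10, minimum total 15), which left 18344. Counts were scaled with TMM factors and tested with edgeR 4.0.16 (robust quasi-likelihood fit, R 4.3.3) in 1 model of the 3 groups over all 12 libraries, at a Benjamini-Hochberg adjusted p under 0.05. The common dispersion was 0.272. The SE printed with a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. It was derived from the test and is not a fitted standard error. Values are CPM, the counts scaled to a common library size with TMM factors, and log2 CPM used a prior count of 2. PBS 1 to 3 were compared with PBS 4 to 6 in the same way as a technical check.

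Named genes followed a fixed rule. For each comparison these were up to 10 genes per direction with the largest log2 fold change among those called, with an average log2 CPM of at least 1, the groups apart in every library, and no predicted or clone symbol. The rule added the 3 members with the smallest p of each list spoken of, Nf1, and Cdkn1a for carboplatin or Dusp6 and Spry4 for selumetinib. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were given as values. Of the genes so allowed, some were left unnamed, and which were named was chosen after the results were seen. Some genes that the rule names are not reported here.

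Genes were grouped in 47 lists of pathways and cell type markers written from general knowledge. Of their 838 genes, 827 were matched by symbol, 6 by ID and 5 not at all. A gene written into several lists was left to 1 of them. Cdkn1a, Mt2, Per1, Nfkbia, Dusp1, Plin4 and Lcn2 were so taken out of the glucocorticoid list. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Of 47 lists 19 passed for carboplatin against PBS, 26 for selumetinib against PBS and 19 for carboplatin against selumetinib. With an estimated correlation 0 passed in each, and with fry, which tests whether a list moves on balance in 1 direction, 8, 0 and 8 passed. The preset test therefore carries little weight. Of the fry values by list, only that of the MEK-ERK output genes in carboplatin against selumetinib is printed below. The other lists that passed with fry are not named. The values with an estimated correlation do not show which they are. The lists spoken of were chosen after their results were seen, 30, 19 and 19 of the 47 in the 3 comparisons. In some alternative setting the direction that camera gives turned for 2, 8 and 2 of these, and for 1, 11 and 6 of the lists not spoken of, and medians near 0 changed sign in others. Among the lists spoken of for carboplatin against PBS, the median, the mean and the camera direction differed in sign for those of adipocyte, apoptosis, DNA repair, fatty acid, newly formed oligodendrocyte, NF-kB, neuron and skeletal muscle genes. They also differed for some lists not spoken of.

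The alternatives fixed in advance were DESeq2 1.42.0, limma voom with quality weights, RLE and upper-quartile factors, no filter, a filter of 1 CPM in 3 libraries, a fold change of at least 2, only the groups compared, PBS 1 to 3 or PBS 4 to 6 as the controls, Y-linked expression as a covariate, the replicate number as a term and each library left out in turn. After the data were seen, fits were added without PBS 1, selumetinib 1 and selumetinib 2, without selumetinib 1 and 2, without carboplatin 1 and 3, with the muscle, retina and neuron scores as covariates, with the Y-linked covariate without PBS 1, with only the 7 libraries with Y-linked counts, and with each treatment relative to the PBS libraries listed before it. Marker lists of hypothalamus, cortex and further muscle genes were also written then, and members already seen were later left out of their tests.

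The tests were checked on simulated counts with 100 genes changed by 2-fold and 100 by 4-fold. For carboplatin against PBS, edgeR recovered 13 and 74 of them over 18063 genes, with 3 false calls in 90, DESeq2 36 and 92 with 48 false calls in 176, and limma voom 13 and 70 with 0 in 83. For selumetinib against PBS, edgeR recovered 15 and 67 over 18074 genes with 3 false calls in 85, DESeq2 40 and 83 with 76 in 199, and limma voom 16 and 68 with 2 in 86. For carboplatin against selumetinib, edgeR recovered 6 and 43 over 18073 genes with 0 false calls in 49, DESeq2 25 and 73 with 55 in 153, and limma voom 7 and 42 with 0 in 49. The limit on false calls that these had to meet was applied to edgeR alone after DESeq2 exceeded it. A list shifted by 2-fold was recovered in each comparison, and 0, 2 and 0 of the other 46 lists were called. Each gene was drawn on its own around its mean over all libraries. The simulated counts therefore hold no tissue difference shared by genes and no library that stands apart. Their false calls, of genes by any tool and of lists, need not hold for the real libraries. No 2 libraries of a group were alike within sampling noise, and no gene that the files list was left out before filtering.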

Results

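RNA with poly(A) tails was sequenced from the optic nerve of mice of a neurofibromatosis (NF1) model. The 12 libraries came from mice given phosphate-buffered saline (PBS, 6 libraries), carboplatin (3 libraries), a platinum drug that cross-links DNA, or selumetinib (3 libraries), an inhibitor of MEK kinases. PBS 1 to 6 held 29510138, 22558698, 29779508, 23632330, 23489372 and 29009101 counts, carboplatin 1 to 3 held 33375754, 27974848 and 32249691, and selumetinib 1 to 3 held 25400782, 24507191 and 21793052. Of the 35275 genes listed, 25593 had a count and 18344 were tested. Dose, schedule, age and sex were not given in the sources used here. The labels do not say that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical in part. PBS 1 and carboplatin 1 had 0 counts of Y-linked genes, unlike the other libraries of their groups. PBS and carboplatin therefore each held more than 1 animal. Nf1 (ENSMUSG00000020716, chromosome 11, 79339693 to 79581612, build mm10), the gene the model is named for, was at 66.7 ± 19.0 CPM in PBS (SD, n = 6), 58.8 ± 1.31 CPM in carboplatin (n = 3) and 71.9 ± 4.45 CPM in selumetinib (n = 3). No wild-type group was used here, so this level checks no label.

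The libraries differed in the share of marker genes of neighbouring tissues and of cell types. Skeletal muscle genes took 7.89% of the counts of PBS 1, against 0.00268% to 0.0537% in PBS 2 to 6, 0.0190% to 0.314% in carboplatin and 0.00189% to 0.00335% in selumetinib. Photoreceptor genes took 0.0976% of carboplatin 1 and 0.171% of carboplatin 3, against 0.00868% of carboplatin 2 and at most 0.0176% of any PBS library. Mature oligodendrocyte genes took 2.66% of PBS 1, 3.81% of selumetinib 1 and 2.76% of selumetinib 2, and 7.85% to 9.79% of the other 9 libraries. Globin and other red blood cell genes took 0.00125% to 0.00808% of the carboplatin libraries, 0.0247% to 0.819% of PBS and 0.0725% to 0.161% of selumetinib. Counts of Y-linked genes were 0 in PBS 1, carboplatin 1 and the 3 selumetinib libraries.

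Carboplatin was compared with PBS to ask how the drug changed expression in the nerve, in a study whose stated subject was oligodendrocytes and myelin. Of the listed genes, 5 of 7 glucocorticoid response genes and 4 of 29 p53 targets rose, and 5 of 17 MHC presentation and 4 of 30 cell cycle genes fell. As lists these gave adjusted p = 0.0824, 0.255, 0.560 and 0.470 with an estimated correlation. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, rose from 38.4 ± 26.9 CPM in PBS (SD, n = 6) to 436 ± 154 CPM in carboplatin (n = 3), a log2 fold change of 3.51 ± 0.49 (SE) with an edgeR adjusted p of 0.00536. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose from 47.4 ± 16.9 to 436 ± 175 CPM (log2 3.20 ± 0.37, adjusted p 0.00189). H2-Aa, a class II major histocompatibility (MHC) chain, fell from 66.3 ± 18.5 to 5.40 ± 1.07 CPM (log2 -3.62 ± 0.49, adjusted p 0.00453). Mki67, a marker of dividing cells, fell from 7.51 ± 6.61 to 0.545 ± 0.267 CPM (log2 -3.76 ± 0.74, adjusted p 0.0278). Of the 18344 genes, 383 changed (288 higher, 95 lower), 248 of them by at least 2-fold.

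Among 7 glucocorticoid response genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median log2 fold change of 2.43 and an adjusted p = 0.0824 with an estimated correlation. Besides Fkbp5 these included Tsc22d3, a glucocorticoid-induced leucine zipper protein (1.35 ± 0.15), and Zbtb16, a transcription factor (2.43 ± 0.36). Of 29 p53 targets 4 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.31 and an adjusted p = 0.255 with an estimated correlation. Bbc3, which encodes the pro-apoptotic protein PUMA, rose by 1.45 ± 0.20, and Trp53inp1 by 1.24 ± 0.22. Of 18 genes of the NRF2 and metal response 4 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.40 and an adjusted p = 0.0824 with an estimated correlation. The metallothionein Mt1 rose from 331 ± 95.9 to 1396 ± 215 CPM (2.08 ± 0.25, adjusted p 0.00246 by edgeR), Mt2 by 1.65 ± 0.29 and the glutathione transferase Gstm1 by 1.01 ± 0.14. Cdkn1a and Mt2, like Per1, Nfkbia and Plin4 below, had first been written as glucocorticoid response genes too. These lists therefore need not mark separate responses. Of 20 apoptosis genes 1 rose (2 adjusted over the list alone), which was Bcl2l1, the gene of the anti-apoptotic BCL-XL (1.57 ± 0.16, adjusted p 0.00137), and of 25 DNA repair genes 1 rose (1 adjusted over the list alone), the excision repair gene Xpa (0.77 ± 0.14). The median of the p53 list was 0.51 without PBS 1, where Cdkn1a was at 90.8 CPM.

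Some antigen presentation and cell division genes gave lower values in carboplatin. Of 17 MHC presentation genes 5 fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -1.05 and an adjusted p = 0.560 with an estimated correlation. With H2-Aa fell H2-Eb1 (-3.45 ± 0.44) and Cd74, the class II invariant chain (-3.01 ± 0.43, edgeR adjusted p 0.00603). Of 15 border macrophage and monocyte genes 1 fell (1 adjusted over the list alone), the chemokine receptor Ccr2 (-3.40 ± 0.65), with a list median of -1.37 and an adjusted p = 0.576 with an estimated correlation. Of 9 neutrophil genes 0 changed by edgeR (0 higher and 3 lower at an unadjusted p under 0.05, 3 lower by DESeq2 and 1 by limma voom), with a median of -2.33, or 0.22 with PBS 1 to 3 as the controls, and an adjusted p = 0.638 with an estimated correlation. At the preset correlation that list passed, but not without PBS 5 (-1.33) or carboplatin 2 (-1.86). Of 20 microglia genes 1 fell (1 adjusted over the list alone), the microglial receptor Fcrls (-1.91 ± 0.41), with a list median of -0.12 and an adjusted p = 0.957 with an estimated correlation. Of the fits without 1 library, those without PBS 1 (-0.25) and carboplatin 2 (-0.35) let that list pass at the preset correlation. Of 30 cell cycle genes 4 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -1.43 and an adjusted p = 0.470 with an estimated correlation. Cenpf (-3.22 ± 0.62) and Kif11 (-2.11 ± 0.48), which act at the kinetochore and the spindle, were among them. Without PBS 1 the medians were -0.47 for MHC presentation, -0.76 for the border macrophages and -0.76 for the cell cycle. The red blood cell list moved with these groups: 5 of its 7 genes fell (7 adjusted over the list alone), Hbb-bs by 6.26 ± 1.34 on the log2 scale, with an adjusted p = 0.245 with an estimated correlation. With PBS 1 to 3 as the controls 0 red blood cell genes and 1 cell cycle gene fell, and 6 and 2 fell with PBS 4 to 6.

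Oligodendrocyte genes moved in both directions. Opalin, a membrane protein of mature oligodendrocytes, fell from 81.7 ± 26.6 CPM in PBS (n = 6) to 15.9 ± 5.13 CPM in carboplatin (n = 3), a log2 fold change of -2.36 ± 0.41 with an edgeR adjusted p of 0.0162. Il33, a cytokine made by oligodendrocytes, fell by 1.30 ± 0.29 on the log2 scale, and Apod, a lipid carrier of oligodendrocytes and astrocytes, rose by 2.62 ± 0.42. The other 25 of 28 mature oligodendrocyte genes did not pass (1 rose and 3 fell adjusted over the list alone), and the list median was -0.14 with an adjusted p = 0.957 with an estimated correlation. Of 15 precursor genes 0 changed by edgeR (1 rose and 1 fell adjusted over the list alone, at an unadjusted p under 0.05 and by DESeq2; 2 and 3 by limma voom), with a median of 0.04. Of 14 genes of newly formed oligodendrocytes 0 changed by edgeR or DESeq2 (1 higher and 1 lower at an unadjusted p under 0.05, 1 and 3 by limma voom), with a median of 0.03. Without PBS 1, whose oligodendrocyte share was low, 1 mature gene rose and 5 fell, and the median was -0.32 with an adjusted p of 0.0388 at the preset correlation. With PBS 1 to 3 as the controls 1 mature gene rose and 0 fell, with a median of 0.0171. With PBS 4 to 6 as the controls 1 rose and 1 fell, with a median of -0.26.

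Of 25 cholesterol biosynthesis genes 3 fell and 0 rose (14 fell adjusted over the list alone), with a median of -0.60 and an adjusted p = 0.424 with an estimated correlation. They were the sterol reductases Tm7sf2 (15.3 ± 1.55 to 8.07 ± 0.269 CPM, log2 -0.93 ± 0.15, edgeR adjusted p 0.0125) and Dhcr7 (-1.22 ± 0.25) and the squalene synthase gene Fdft1 (-0.69 ± 0.14). With PBS 1 to 3 as the controls 1 cholesterol gene fell, and 5 fell with PBS 4 to 6. Among 19 fatty acid and sphingolipid genes 1 rose and 1 fell (3 and 2 adjusted over the list alone): Acaca, an acetyl-CoA carboxylase, by 1.84 ± 0.27, and the elongase gene Elovl6, which fell by 1.40 ± 0.27. Of 20 astrocyte genes 3 rose (6 adjusted over the list alone), the angiotensinogen gene Agt by 1.91 ± 0.30, Htra1 by 1.51 ± 0.24 and Aldh1l1 by 1.10 ± 0.25, with a median of 0.53, or 0.30 without PBS 1, and an adjusted p = 0.576 with an estimated correlation. Of 16 reactive astrocyte genes 0 changed by edgeR (1 rose adjusted over the list alone, at an unadjusted p under 0.05 and by DESeq2; 4 rose and 1 fell by limma voom). Among 30 ribosomal protein genes 1 rose (1 adjusted over the list alone), Rpl3 by 0.79 ± 0.17, with a median of 0.51 and an adjusted p = 0.576 with an estimated correlation. The neuronal activity genes Arc (-2.71 ± 0.39) and Nr4a2 (-0.96 ± 0.20) fell, 2 of 19 immediate early genes (2 rose and 3 fell adjusted over the list alone). The inhibitor of NF-kB Nfkbia rose by 1.64 ± 0.28, as 1 of 19 NF-kB and cytokine genes (1 adjusted over the list alone), and the clock gene Per1 rose by 1.28 ± 0.28, as 1 of 16 clock genes (2 adjusted over the list alone), a list (median 0.12; adjusted p = 0.705 with an estimated correlation) that passed at the preset correlation without PBS 2 (0.10) and with PBS 4 to 6 as the controls (0.50). Of 20 MEK-ERK output genes and of 17 genes of the RAS pathway 0 changed by edgeR or DESeq2 (0 higher and 1 lower, and 0, at an unadjusted p under 0.05; 4 higher and 1 lower, and 5 lower, by limma voom), with medians of 0.11 and -0.17. Nf1 had a log2 fold change of -0.18 ± 0.25 with an adjusted p of 0.753, or -0.36 and past the threshold without PBS 1.

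The 10 largest rises under the naming rule included Zfand4, which encodes a zinc finger protein (chromosome 6, 116264222 to 116330302; 2.73 ± 1.13 to 51.5 ± 7.26 CPM, log2 4.23 ± 0.43, edgeR adjusted p 0.00137), Hif3a, a hypoxia-inducible factor (4.15 ± 0.58), Itgad, an integrin subunit (4.06 ± 0.50), and Pla2g3, a secreted phospholipase (3.98 ± 0.42). The other 6 were Slc24a1 (5.75 ± 0.92), a photoreceptor exchanger, and Ttr (5.42 ± 1.16), Otx2 (5.41 ± 1.20), Mfrp (5.26 ± 0.87), Lrat (4.74 ± 0.98) and Slc16a8 (4.43 ± 0.91), genes known from the pigment epithelium of the eye. Of 17 retina genes 1 rose (15 adjusted over the list alone), the photoreceptor disc gene Rom1 by 1.62 ± 0.27, with a median of 4.46 and an adjusted p = 0.249 with an estimated correlation. Of 8 pigment cell genes 1 rose (7 adjusted over the list alone), the melanosome gene Oca2 by 5.60 ± 1.25, with a median of 5.49, or 2.00 without carboplatin 2, and an adjusted p = 0.290 with an estimated correlation. Without carboplatin 2, Ttr was at 2.97, Mfrp at 3.42, Lrat at 2.60, Slc16a8 at 2.29 and Oca2 at 3.52, none of them past the threshold. Plin4 rose by 3.32 ± 0.72 and was the only 1 of 6 adipocyte genes called (1 adjusted over the list alone), a call lost in 10 of the 12 fits without 1 library. The median of that list was -2.15, with 2 of 6 positive and an adjusted p = 0.802 with an estimated correlation, or 3.31 without PBS 1. It passed at the preset correlation without PBS 1 or carboplatin 3 (-1.77), and in some other settings. Thsd7b fell by 3.26 ± 0.69. The 19 neuron genes (median -0.44) gave 0 calls by edgeR, with 2 higher and 3 lower at an unadjusted p under 0.05, 2 lower by DESeq2, and 4 higher and 2 lower by limma voom. The 29 nuclear oxidative phosphorylation genes (median -0.76, or 0.33 without PBS 1) and the 18 skeletal muscle genes (median -3.05) gave 0 calls by edgeR and at an unadjusted p under 0.05, and 5 and 3 higher by limma voom. DESeq2 called 0 of the 6 oxidative phosphorylation genes to which it gave an adjusted p, and gave none to the muscle genes. Without PBS 1 the oxidative phosphorylation list passed at the preset correlation, while with all libraries it had an adjusted p = 0.957 with an estimated correlation. The muscle list passed upward at the preset correlation against its median (adjusted p 0.0136; adjusted p = 0.910 with an estimated correlation), and without PBS 1 its median was 3.50. It no longer passed without PBS 4 (-3.23), PBS 5 (-3.23), PBS 6 (-3.31), carboplatin 1 (-3.56) or carboplatin 2 (-3.29).

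Key genes were placed on build mm10. Cdkn1a (ENSMUSG00000023067) spans 29090976 to 29100727 of chromosome 17, and Fkbp5 (ENSMUSG00000024222) spans 28399094 to 28517527 there. H2-Aa (ENSMUSG00000036594) lies at 34282744 to 34287823 of the same chromosome. Opalin (ENSMUSG00000050121) spans 41061710 to 41077113 of chromosome 19. Mt1 (ENSMUSG00000031765) spans 94179082 to 94180327 of chromosome 8. Apod (ENSMUSG00000022548) spans 31296192 to 31314808 of chromosome 16. Cdkn1a overlaps AC167363.2, Pla2g3 overlaps Inpp5j, Fdft1 overlaps Ctsb, Htra1 overlaps Fgfr2 and Xpa overlaps Ncbp1, each on the opposite strand, and Tm7sf2 overlaps Vps51 on its own strand. The strand used in counting was not given, so these values are uncertain, as are those of near-identical copies such as Hbb-bs and of Rpl3, whose reads can fall on pseudogenes.

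The test behind these calls was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05, 3035 genes passed (1489 higher, 1546 lower), and the median log2 fold change of all genes was -0.11, so changes stand relative to that shift. Of the 383 genes, 376 had all carboplatin libraries on one side of all PBS libraries, as did 12.2% of all genes, against 2.38% by chance. The count was 1941 without PBS 1, 192 without PBS 4, 176 without PBS 5 and 168 without PBS 6. It was 119 without carboplatin 1, 194 without carboplatin 2, 73 without carboplatin 3, 245 without selumetinib 1 and 582 without selumetinib 3. It was 119 with the muscle, retina and neuron scores as covariates, and 14 without carboplatin 1 and 3. Of the 54 named genes called, Zfand4, Hif3a, Itgad, Pla2g3, H2-Aa, H2-Eb1, Bcl2l1, Tsc22d3, Fkbp5, Zbtb16, Mt1, Gstm1, Bbc3 and Cdkn1a passed whichever library was left out. The other 40 were lost in at least 1 such fit: 6 without PBS 2, 14 without PBS 3, 23 without PBS 4, 22 without PBS 5, 24 without PBS 6, 30 without carboplatin 1, 25 without carboplatin 2, 37 without carboplatin 3, 19 without selumetinib 1, 16 without selumetinib 2 and 1 without selumetinib 3.

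**Figure D1:**
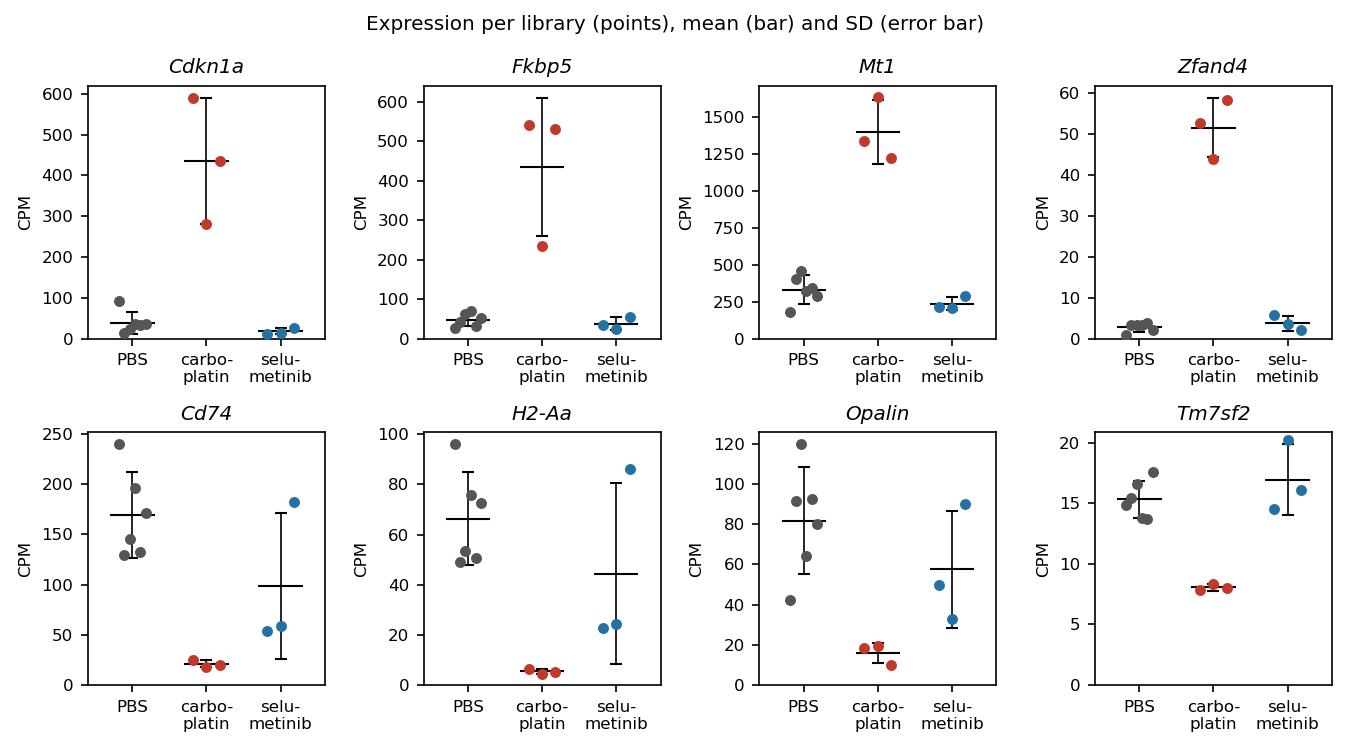
Expression (CPM) of 8 genes in each of the 12 libraries, with points for libraries, and the mean and SD of each group. Cdkn1a, Fkbp5, Mt1 and Zfand4 lie above all PBS libraries in the 3 carboplatin libraries, and Cd74, H2-Aa, Opalin and Tm7sf2 lie below them.

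Selumetinib was compared with PBS to ask how a MEK inhibitor changed expression in the nerve. The 3 selumetinib libraries had 0 Y-linked counts and 19490 to 22968 counts of Xist, while PBS 2 to 6 had 3377 to 5866 Y-linked counts, so sex and this treatment are confounded apart from PBS 1. No gene passed: edgeR called 0 of 18344 genes, with a smallest adjusted p of 0.0884, while 4410 had an unadjusted p under 0.05 (2575 higher, 1835 lower), DESeq2 called 2272 and limma voom 10165. With Y-linked expression as a covariate edgeR called 2558, and 0 when PBS 1 was also left out. Dusp6, an ERK phosphatase and a target of the pathway, was at 26.6 ± 10.4 CPM in PBS (SD, n = 6) and 17.5 ± 2.76 CPM in selumetinib (n = 3), a log2 fold change of -0.61 ± 0.29 (SE) with an adjusted p of 0.230, or -0.36 without PBS 1. Spry4, a further target, had 0.22 ± 0.26 (adjusted p 0.597), or 0.0116 without selumetinib 1, 0.15 without PBS 3 and 0.38 without selumetinib 3, and Nf1 had 0.11 ± 0.25 (adjusted p 0.801). The smallest p-values of higher genes belonged to Pomc, the precursor of hypothalamic and pituitary peptides (4.88 ± 0.78), Fgf9 (2.93 ± 0.49), Syt6 (3.63 ± 0.61), Syt2 (3.57 ± 0.63) and Hs3st4 (4.80 ± 0.84), each at 0.0884. Those of lower genes belonged to Cnksr3 (-0.73 ± 0.16), Rel (-1.19 ± 0.26), the cytokine gene Tgfb1 (-1.02 ± 0.22), Amd2 (-1.48 ± 0.33) and Lpcat3 (-0.52 ± 0.12), also at 0.0884.

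Selumetinib 1 and 2 stood apart from selumetinib 3 in most of these groups. Of 19 neuron genes 0 passed over all genes, and 13 rose and 1 fell adjusted over the list alone, with a median of 2.04 and an adjusted p = 0.529 with an estimated correlation. Nefm (2.14 ± 0.42), Thy1 (2.04 ± 0.41) and the glutamate transporter Slc17a6 (5.10 ± 1.02) had the smallest p, and Slc17a6 was at 111 ± 97.1 CPM in selumetinib against 3.24 ± 2.90 CPM in PBS. Of 22 node of Ranvier genes 6 rose adjusted over the list alone and 0 over all genes, among them Cntnap1, the paranodal protein Caspr (1.56 ± 0.35), with a list median of 0.50 and an adjusted p = 0.592 with an estimated correlation. The mature oligodendrocyte list, with 0 calls in 28 genes, had a median of -0.62 and an adjusted p = 0.570 with an estimated correlation, Mal at -0.67 ± 0.36 and Gsn at -1.06 ± 0.44. It stood beside oligodendrocyte shares of 3.81% and 2.76% in selumetinib 1 and 2 and 8.87% in selumetinib 3. The medians of newly formed oligodendrocyte and precursor genes were -0.39 and -0.33 (adjusted p = 0.592 and 0.770 with an estimated correlation), with 0 calls by edgeR and DESeq2. At an unadjusted p under 0.05, 2 and 1 were lower, and limma voom called 8 lower in each and 1 precursor gene higher. DESeq2 called 11 neuron genes and 7 node genes higher and 0 mature oligodendrocyte genes, and limma voom called 16 neuron genes higher and 1 lower, 12 node genes higher and 6 lower, and 28 mature oligodendrocyte genes lower.

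Microglia, disease-associated glia, reactive astrocyte and immediate early lists had medians below 0, with no call over all genes. The 20 astrocyte genes had a median near 0, at -0.0434, with 9 of them positive and an adjusted p = 0.975 with an estimated correlation. They gave 0 calls by edgeR, 1 higher and 1 lower at an unadjusted p under 0.05, 1 higher by DESeq2, and 5 higher and 10 lower by limma voom. At the preset correlation they passed upward with the Y-linked covariate (0.53) and downward in 3 fits added after the data were seen. The values were -0.56 for the median of 20 microglia genes (1 fell adjusted over the list alone), with Itgam at -1.03 ± 0.23, and -0.74 for 20 disease-associated glia genes (7 fell adjusted over the list alone), with the lysosomal gene Cd68 at -0.89 ± 0.21, each with an adjusted p = 0.529 with an estimated correlation. In 16 reactive astrocyte genes 11 fell and 1, Amigo2 (2.45 ± 0.44), rose adjusted over the list alone (median -1.12; adjusted p = 0.529 with an estimated correlation). Immediate early genes had a median of -1.21, with 8 of 19 lower adjusted over the list alone, Jun at -0.81 ± 0.20, Fos at -1.28 ± 0.35 and Cyr61 at -1.26 ± 0.36 (adjusted p = 0.529 with an estimated correlation). The median of the 20 MEK-ERK output genes was -0.47, with 0 called in either way, Spred3 at 1.30 ± 0.39, and an adjusted p of 0.103 with the preset correlation and adjusted p = 0.529 with an estimated correlation. Of 17 RAS pathway genes 5 rose adjusted over the list alone, with Araf, which overlaps Syn1 on the other strand, at 0.67 ± 0.19. DESeq2 called 1 MEK-ERK output gene higher and 1 lower, 9 immediate early, 6 disease-associated glia and 1 microglia gene lower, and 7 reactive astrocyte genes lower and 1 higher. Of the MEK-ERK output genes 1 was higher and 3 were lower at an unadjusted p under 0.05, and 2 and 8 by limma voom. The medians were -0.86 for 25 interferon response genes, -0.97 for 17 MHC presentation genes, -0.45 for 7 glucocorticoid response genes, with Sgk1 at -1.82 ± 0.52, and -0.42 for 18 NRF2 and metal genes, each with an adjusted p = 0.529 with an estimated correlation. They were -0.32 for 29 p53 targets (adjusted p = 0.569 with an estimated correlation) and -0.30 for 25 cholesterol biosynthesis genes (adjusted p = 0.575 with an estimated correlation). The median of 18 skeletal muscle genes was -10.74, all 18 lower adjusted over the list alone (adjusted p = 0.592 with an estimated correlation), beside the muscle RNA of PBS 1, and -4.21 without PBS 1.

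Leaving out selumetinib 3 raised the count of changed genes from 0 to 4089, and 25 of the 28 named genes then passed. The medians of the mature oligodendrocyte, interferon and reactive astrocyte lists were then -1.30, -1.68 and -1.78, against -0.30, -0.51 and -0.76 without selumetinib 2. The node of Ranvier and p53 lists no longer passed at the preset correlation without PBS 1 (0.43 and -0.17), nor did the p53 list without selumetinib 2 (-0.21). Without PBS 1 the medians of the immediate early and MHC lists were -0.73 and -0.60. Without selumetinib 3 they were -1.30 for disease-associated glia, -1.05 for glucocorticoid, -1.55 for MHC, -0.93 for microglia, -0.54 for cholesterol and -0.55 for p53 genes. Without selumetinib 2 they were -0.47 for disease-associated glia, -0.35 for microglia and -0.16 for cholesterol genes, and -0.19 for the last without selumetinib 1. At the preset correlation the newly formed oligodendrocyte list passed without PBS 1 (-0.49), carboplatin 1 (-0.39) or selumetinib 3 (-0.61), the precursor list without PBS 1 (-0.42) and the MEK-ERK output list without selumetinib 1 (-0.45). Without selumetinib 2 these 3 medians were -0.22, -0.14 and -0.27, and the lists did not pass. Some directions turned when several libraries were left out. Without PBS 1, selumetinib 1 and selumetinib 2 the medians were 0.13 for interferon, 0.23 for MHC and 0.0317 for p53 genes, and -0.0380 for node of Ranvier genes. With the Y-linked covariate they were 0.11 for cholesterol, 0.11 for mature oligodendrocyte and 0.14 for microglia genes. Leaving out any other library gave 0 genes.

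Carboplatin was compared with selumetinib directly, which is also the test of the difference between their effects if the 6 PBS libraries are taken as 1 group. Sgk1, a kinase induced by glucocorticoids, was at 1084 ± 233 CPM in carboplatin (SD, n = 3) and 40.0 ± 16.1 CPM in selumetinib (n = 3), a log2 fold change of 4.76 ± 0.64 (SE) with an edgeR adjusted p of 0.00486. Cdkn1a was higher by 4.64 ± 0.67 (adjusted p 0.00667), Fkbp5 by 3.54 ± 0.49 and Mt1 by 2.56 ± 0.32. Of the neuronal genes, Stmn2 was lower in carboplatin, at 9.20 ± 3.64 CPM against 151 ± 103 CPM (-4.03 ± 0.92, adjusted p 0.0225). Of 18344 genes 2568 differed, 1036 higher and 1532 lower in carboplatin, with 144 of the 2568 on chromosome X or Y, where 644 tested genes lie. Carboplatin 2 and 3 had 4012 and 5967 Y-linked counts, against 0 in carboplatin 1 and in selumetinib, so sex and treatment are partly confounded here too. The balance of higher and lower genes depended on the libraries. It was 223 and 69 without carboplatin 1, 337 and 137 without carboplatin 2 and 165 and 49 without carboplatin 3. It was 86 and 48 without selumetinib 1, 103 and 45 without selumetinib 2, and 2243 and 2039 with the Y-linked covariate. The libraries are listed with PBS 1 to 3 before carboplatin and PBS 4 to 6 before selumetinib, and these PBS libraries differed from each other. A fit chosen after the data were seen took each treatment relative to the PBS libraries listed before it. In it 22 genes passed (21 higher, 1 lower), 20 of them among the 2568. Of the named genes these included Bcl2l1 (2.00), Tsc22d3 (1.70) and Lcn2 (8.03). The other calls did not pass in that fit, which has 3 controls per treatment, though all 2568 kept their direction. A difference between the 2 sets of libraries stays open for them.

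Of the 7 glucocorticoid response genes 6 were higher (7 adjusted over the list alone; adjusted p = 0.220 with an estimated correlation), of 18 NRF2 and metal genes 10 (10 adjusted over the list alone; adjusted p = 0.0875 with an estimated correlation) and of 29 p53 targets 9 (10 adjusted over the list alone; adjusted p = 0.538 with an estimated correlation), with none lower. Their medians were 2.89, 1.02 and 0.87. Tsc22d3 was higher by 1.78 ± 0.18, Gstm1 by 1.04 ± 0.17, Mt2 by 2.12 ± 0.36, Bbc3 by 1.64 ± 0.24 and Trp53inp1 by 1.43 ± 0.26. Of 20 apoptosis genes 3 were higher (3 adjusted over the list alone; adjusted p = 0.666 with an estimated correlation), with Bcl2l1 at 1.86 ± 0.20, and of 19 NF-kB and cytokine genes 2 (2 adjusted over the list alone; adjusted p = 0.666 with an estimated correlation), with Nfkbia at 2.57 ± 0.36. Of 16 reactive astrocyte genes 4 were higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.538 with an estimated correlation), with the siderophore binder Lcn2 at 5.85 ± 1.04, and of 20 astrocyte genes 5 were higher (8 adjusted over the list alone; adjusted p = 0.706 with an estimated correlation). Ribosomal protein genes were higher in 4 of 30 (15 adjusted over the list alone; median 0.86; adjusted p = 0.666 with an estimated correlation). Immediate early genes went both ways, with 3 of 19 higher and 2 lower (8 and 5 adjusted over the list alone), with a median of 0.92 and an adjusted p = 0.753 with an estimated correlation. As a list they passed at the preset correlation without PBS 1 (0.90) and in some other settings. Without selumetinib 3 the medians were 2.22 for reactive astrocyte (1.36 with all libraries), 1.33 for NF-kB (0.68) and 0.49 for apoptosis genes (0.27). The NF-kB median was 0.45 without selumetinib 2, and the apoptosis list no longer passed without PBS 1 (0.25) or selumetinib 2 (0.15).

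Of 28 mature oligodendrocyte genes 1, Apod (3.44 ± 0.55), was higher and 2, Opalin (-1.85 ± 0.43) and Il33 (-1.10 ± 0.32), were lower (1 and 1 adjusted over the list alone), with a median of 0.43 and an adjusted p = 0.799 with an estimated correlation, beside the low oligodendrocyte share of selumetinib 1 and 2. That median was 0.24 without selumetinib 1, 0.14 without selumetinib 2 and 1.00 without selumetinib 3, and the list passed at the preset correlation with all libraries but not without selumetinib 1 or 2, PBS 2 (0.43), PBS 4 (0.43) or carboplatin 2 (0.39). The Il33 call was lost in 11 of the 12 fits without 1 library, all but that without PBS 1, and its value was -0.73 without selumetinib 3. Without selumetinib 3 Cd74 was at -1.44. Of 17 MHC presentation genes 5 were lower (5 adjusted over the list alone; median -0.08, or -0.17 without carboplatin 2, 0.0190 without carboplatin 3, -0.32 without selumetinib 1, -0.32 without selumetinib 2 and 0.49 without selumetinib 3), with H2-Aa at -3.04 ± 0.50 and Cd74 at -2.22 ± 0.44. Of 19 neuron genes 10 were lower (1 higher and 13 lower adjusted over the list alone; median -2.49; adjusted p = 0.666 with an estimated correlation), among them Thy1 (-2.49 ± 0.52) and Syn1 (-3.57 ± 0.77), which overlaps Araf. These values stand beside neuron scores of selumetinib 1 and 2 that lay 2.37 and 2.35 above the mean of the other libraries without PBS 1. Against PBS, carboplatin gave 0 neuron calls and a median of -0.44. The brain-expressed genes Dgkk (-9.04 ± 1.76) and Glra2 (-8.39 ± 1.80) had the largest falls named. Node of Ranvier genes were higher in 1 and lower in 5 of 22 (1 and 8 adjusted over the list alone), and 3 of 17 RAS pathway genes were lower (5 adjusted over the list alone). The 20 MEK-ERK output genes gave 0 calls by edgeR, 2 higher and 1 lower by DESeq2, 9 and 3 by limma voom, and 3 and 1 at an unadjusted p under 0.05 (median 0.29; adjusted p = 0.538 with an estimated correlation), and passed as a list at the preset correlation without selumetinib 1 (0.23) and in 1 added fit, without carboplatin 1 and 3 (0.41), and with fry (adjusted p 0.0191). The MEK-ERK median was 0.12 without carboplatin 2 and 0.59 without selumetinib 3. Retina genes were higher in 11 of 17 (14 adjusted over the list alone; adjusted p = 0.538 with an estimated correlation), with the rod gene Gnat1 at 10.47 ± 3.03, and pigment cell genes in 3 of 8 (7 adjusted over the list alone; adjusted p = 0.538 with an estimated correlation), with a median of 5.86, or 2.84 without carboplatin 2. Rpe65, of the pigment epithelium, was at 11.4, 261 and 51.5 CPM in carboplatin 1 to 3 and had 0 counts in selumetinib, and was no longer called without any 1 of the carboplatin libraries, selumetinib 1 or selumetinib 2. Of 7 red blood cell genes 4 were lower (6 adjusted over the list alone; adjusted p = 0.666 with an estimated correlation), and the 18 skeletal muscle genes gave 0 calls by edgeR and no adjusted p by DESeq2, 4 higher by limma voom and 3 higher at an unadjusted p under 0.05 (median 7.82, or -3.79 relative to the PBS libraries listed before each treatment; adjusted p = 0.683 with an estimated correlation).

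At an unadjusted p under 0.05, 5782 genes passed by edgeR, and 41.7% of all genes had the 2 groups apart, against 10% by chance. The count was 5974 without PBS 1 and 1705 without PBS 5. It was 292 without carboplatin 1, 474 without carboplatin 2, 214 without carboplatin 3, 134 without selumetinib 1, 148 without selumetinib 2 and 4788 without selumetinib 3. It was 5 without selumetinib 1 and 2, 22 relative to the PBS libraries listed before each treatment, and 0 with the muscle, retina and neuron scores as covariates. Of the 47 named genes called, Bcl2l1, Tsc22d3, Sgk1, Fkbp5, Nfkbia, Mt1, Gstm1, Cdkn1a, Bbc3 and Rom1 passed whichever library was left out. The others were lost in at least 1 such fit: 3 without PBS 2, 4 without PBS 3, 7 without PBS 4, 8 without PBS 5, 8 without PBS 6, 31 without carboplatin 1, 25 without carboplatin 2, 33 without carboplatin 3, 33 without selumetinib 1, 32 without selumetinib 2 and 3 without selumetinib 3.

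**Figure D2:**
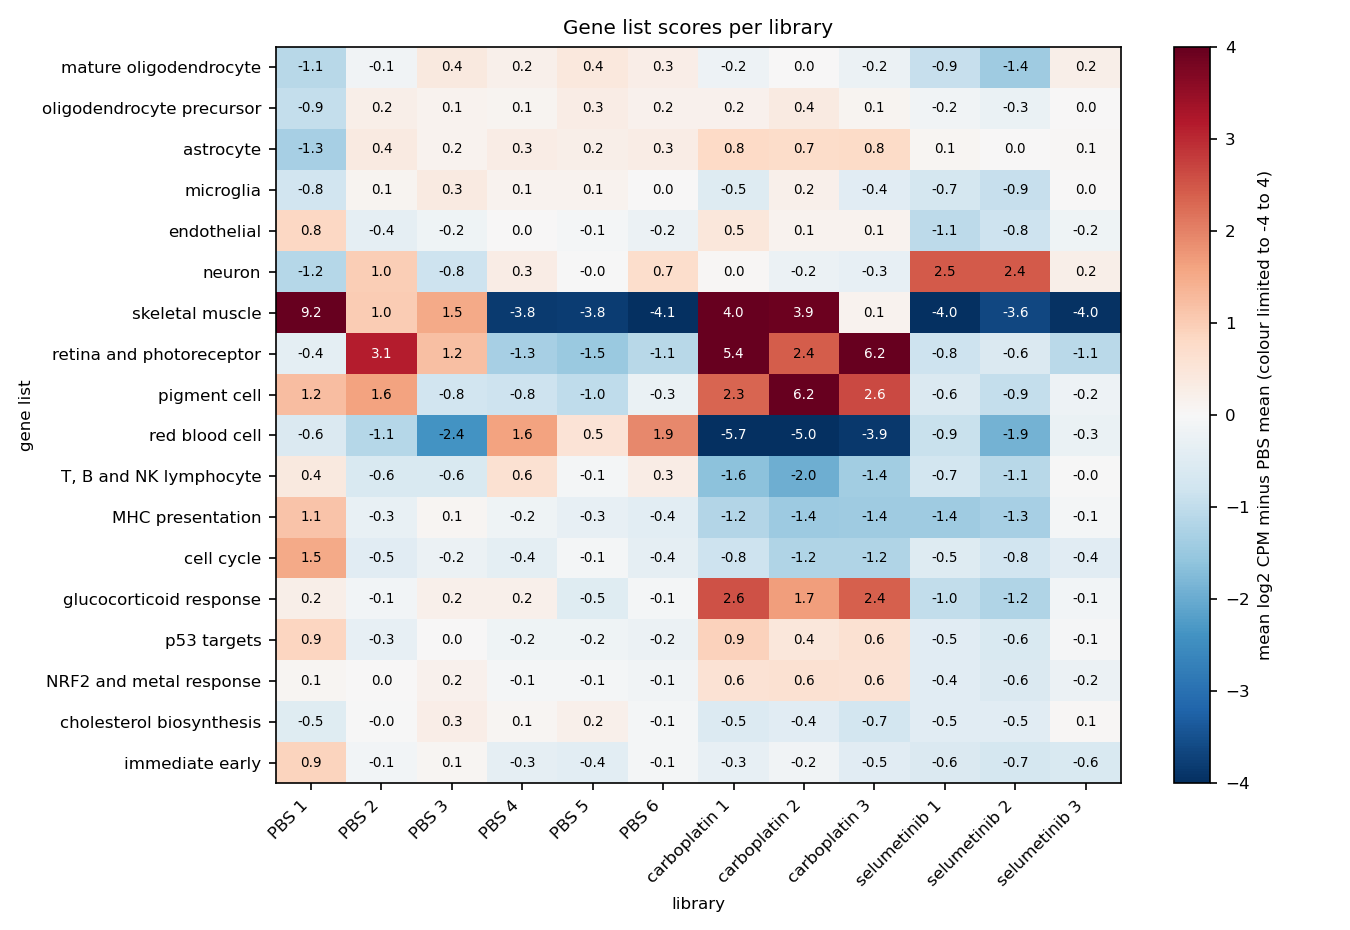
Heat map of 18 gene list scores (mean log2 CPM of the members) in each library, minus the mean of the 6 PBS libraries, with lists as lines and libraries as columns. The glucocorticoid score is highest in the 3 carboplatin libraries, the neuron score in selumetinib 1 and 2, and the muscle score in PBS 1, followed by carboplatin 1 and 2.

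The treatments shared the PBS libraries, so their fold changes were compared with simulated unchanged groups. By edgeR 0 genes were called in both comparisons, beside 3035 and 4410 at an unadjusted p under 0.05, while DESeq2 gave 41 shared genes and limma voom 1530. Across genes, which are not independent replicates, the fold changes correlated at 0.113 with a covariance of 0.167, and 50.0% of genes had the same sign. Over 30 simulated draws 61.0% had it (60.1% to 61.5%), the correlation was 0.321 (0.271 to 0.376) and the covariance 0.149 (0.124 to 0.180). The observed covariance exceeded the simulated mean by 0.0182, less than the range of the draws. The observed correlation and same-sign share lay below every draw. Each gene was drawn on its own around its PBS mean, so the draws hold no tissue differences shared by genes. They therefore cannot decide whether the treatments share an effect. With the PBS libraries split between the treatments in 20 ways, the correlation had a median of -0.284 (-0.670 to 0.0262) and the covariance -0.398, with 0 shared genes.

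The PBS libraries were numbered 1 to 6 in the labels, and numbers 1 to 3 were compared with 4 to 6 as a technical check. By edgeR 1 gene differed, Dbp, a transcription factor whose level follows the daily clock, at 195 ± 38.2 CPM in PBS 1 to 3 and 36.1 ± 4.62 CPM in PBS 4 to 6 (SD, n = 3 each), a log2 difference of 2.44 with an adjusted p of 0.00954. Without PBS 1 the count was 10, Dbp being at 2.24 with an adjusted p of 0.0147. Among those 10, Rbm3 (1.00) was higher in PBS 2 and 3, and the endoplasmic reticulum chaperone genes Hspa5 (-1.25), Sdf2l1 (-1.14) and Manf (-1.01) were lower. Dbp and the other genes of this paragraph were chosen after their values were seen. A clock score, the mean log2 CPM of Dbp, Nr1d1, Nr1d2, Tef, Per3 and Ciart minus that of Arntl, Npas2, Clock and Cry1, was 2.40 ± 0.306 in PBS 1 to 3 and 0.492 ± 0.0630 in PBS 4 to 6, a difference of 1.91 with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allow. It was 1.41 ± 0.0400 in carboplatin and 1.38 ± 0.117 in selumetinib, between the PBS libraries of either run of numbers. With only PBS 1 to 3 as controls carboplatin changed 112 genes, and with only PBS 4 to 6 it changed 502.

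**Figure D3:**
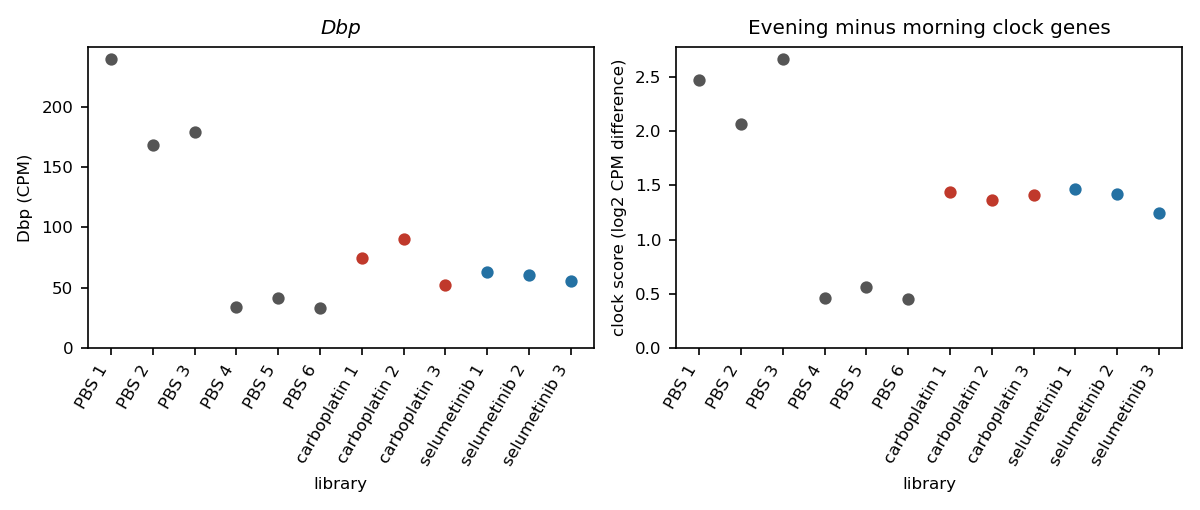
Expression (CPM) of Dbp and the clock score (log2) in each of the 12 libraries by group. PBS 1 to 3 lie above and PBS 4 to 6 below the carboplatin and selumetinib libraries in the score.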

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

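Both tests on PBS 1 in this part, on the oligodendrocyte share and on the further muscle genes, were chosen in their present form after their results were seen.

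Of 41 measures over the 6 PBS libraries, 23 had 1 library whose gap to its nearest neighbour, as a share of the whole range, exceeded the 95% critical share of Dixon's test for 6 samples, which chance gives in about 1 in 20 groups. The measures share their libraries and are not independent. PBS 1 was that library in 22 of them. Its TMM factor was 0.728 (the other 5 at 1.02 to 1.06), its mitochondrial share 10.6% of the counts (2.85% to 4.36%) and the share of its 10 most abundant genes 14.5% (10.9% to 12.2%). Its list scores, in mean log2 CPM, were high for p53 targets (4.73), MHC presentation (6.44), cell cycle (3.48), ribosomal protein (9.20), nuclear oxidative phosphorylation (9.25), immediate early (4.32), apoptosis (4.80) and adipocyte genes (6.32). They were low for fatty acid and sphingolipid synthesis (6.63), astrocytes (6.95), mature (8.20) and newly formed oligodendrocytes (4.98), precursors (4.43), microglia (5.24), the RAS pathway (5.87) and the node of Ranvier (4.06). Nf1 was at 29.1 CPM there (66.7 to 78.6 in the other 5), Cdkn1a at 90.8 (14.1 to 34.6) and Dusp6 at 47.6 (20.9 to 24.9). In PBS 3 Spry4 was at 5.71 CPM, against 7.68 to 8.86 in the other 5.

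Skeletal muscle and keratin genes were high in PBS 1. A tissue other than the nerve in place of it is argued against by the oligodendrocyte genes, whose share of PBS 1 was 31.1% of the mean of PBS 2 to 6. Muscle carried beside the nerve remains a candidate explanation: 10 further muscle genes that were in no earlier list lay above the mean of PBS 2 to 6 by a median of 8.05 on the log2 scale, with Eno3 at 4024 CPM against 6.43 to 31.0 and Cox6a2 at 1102 CPM against at most 7.25. Actc1 was left out because its value had been seen before the genes were chosen. The endothelial score was also higher than in PBS 2 to 6, by 1.01, and the neuron score was lower, at -1.38. The labels put PBS 1 in the PBS group, so no biological explanation was tested.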

How the results depend on the processing

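Fits without PBS 1, selumetinib 1 and selumetinib 2, without selumetinib 1 and 2, without carboplatin 1 and 3, with the muscle, retina and neuron scores as covariates, and with only Y-linked libraries or the Y-linked covariate without PBS 1, and with each treatment relative to the PBS libraries listed before it were chosen after seeing the data, and where 1 library of an arm was left it was assumed to vary like the others. Carboplatin against PBS (383 genes) gave 1469 with DESeq2 (761 higher, 708 lower), 5470 with limma voom (3137 and 2333), 248 at 2-fold or more, 112 with PBS 1 to 3 as the controls (96 and 16), 635 with the Y-linked covariate, 3073 without PBS 1, selumetinib 1 and 2, 119 with the 3 scores, 941 with the Y-linked covariate without PBS 1, 1716 with only Y-linked libraries and 14 without carboplatin 1 and 3, and leaving out 1 library gave 73 to 1941. The 14 came from fewer libraries; of the other differences the cause was not tested. Selumetinib against PBS (0 genes) gave 2272, 10165 and 2558 with DESeq2, limma voom and the Y-linked covariate, and 0 to 4089 leaving out 1 library, the highest without selumetinib 3. Carboplatin against selumetinib (2568) gave 4620, 10788 and 4282 with the same 3, 516 without PBS 1, selumetinib 1 and 2, 5 without selumetinib 1 and 2, 0 with the 3 scores, 569 with the Y-linked covariate without PBS 1, 11 without carboplatin 1 and 3, 22 relative to the PBS libraries listed before each treatment, and 134 to 5974 leaving out 1 library. The genes called in both (0) numbered 41, 1530 and 44 with DESeq2, limma voom and the Y-linked covariate, and 0 to 82 leaving out 1 library. PBS 1 to 3 against 4 to 6 (1) gave 2 with no filter, 555 with DESeq2 and 10 without PBS 1. Of the lists called, 19, 26 and 19, the estimated correlation left 0, 0 and 0 and fry 8, 0 and 8, and for selumetinib against PBS 9 were called without PBS 1, selumetinib 1 and 2, 10 without selumetinib 1 and 2 and 17 with the 3 scores. Some directions reversed. With the 3 scores Gnat1 was at -0.37 in carboplatin against selumetinib. Gnat1 is itself a member of the retina list whose score is a covariate there. That fit takes out the difference it shares with the list and cannot test its direction. Against PBS in carboplatin, the muscle list passed upward in the main setting, though its median is -3.05, and reversed with PBS 1 to 3 as the controls (-4.05). The oxidative phosphorylation median was 0.32 without PBS 1, selumetinib 1 and 2, and 0.26 both with the Y-linked covariate without PBS 1 and with only Y-linked libraries, and leaving out 1 library it ranged from -0.91 to 0.33. In selumetinib against PBS the Y-linked covariate gave cholesterol 0.11, mature oligodendrocyte 0.11 and microglia 0.14. Without PBS 1, selumetinib 1 and 2, astrocyte was at -0.29, interferon at 0.13, mature oligodendrocyte at -0.0095, MHC at 0.23, node at -0.0380 and p53 at 0.0317. Without selumetinib 1 and 2, cholesterol was at 0.0230, interferon at -0.0899 and mature oligodendrocyte at 0.14. With the Y-linked covariate without PBS 1, astrocyte was at -0.21. With the 3 scores, astrocyte was at -0.44, interferon at 0.0927, node at -0.19 and p53 at 0.0524. Carboplatin against selumetinib gave mature oligodendrocyte 0.0165 with the Y-linked covariate, -0.28 without PBS 1, selumetinib 1 and 2, and -0.28 without selumetinib 1 and 2, and the muscle list -3.79 relative to the PBS libraries listed before each treatment. Of 55, 28 and 50 named genes in the 3 comparisons, 1147 of 1648, 728 of 812 and 907 of 1399 values kept their direction and side of the threshold, and of the list values 772 of 840, 425 of 513 and 422 of 494 did. With those controls the direction of the muscle test turned while its median stayed below 0. Apart from Gnat1, the cause of these reversals was not tested.

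The replicate block, over replicates 1 to 3 of each group, gave 2, 2 and 41 genes in the 3 comparisons, 2 genes in both, and turned the muscle list of carboplatin against PBS (-2.01). The labels do not say that the numbers pair the samples, and the values do not settle it. Same-number correlations ran from -0.142 to 0.296, and those of different numbers from -0.382 to 0.331. Still, 6 of the 9 libraries correlated best with a library of their own number. No chance level was computed for this count, and matches between libraries can be mutual, so they are not independent. PBS 1 and carboplatin 1, which matched at 0.222, also both had 0 Y-linked counts. A pairing therefore stays open and is not shown.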

Other observations

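The tests on retina, muscle or neuronal tissue and on sex in the carboplatin response, on the hour of collection, on the oligodendrocyte share, on selumetinib 3 and, in its present form, on the hypothalamus were chosen after their results were seen; the splits of the libraries were set before.

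Avp and Oxt, of the peptide genes in the hypothalamus list, had counts in the optic nerve libraries of every group, while Pmch and Agrp were at most 0.272 and 0.634 CPM in carboplatin. Avp, the vasopressin precursor, was at 22.5 to 435 CPM in PBS, 20.4 to 460 CPM in carboplatin and 292 to 1034 CPM in selumetinib. Oxt, the oxytocin precursor, was at 5.67 to 144 CPM in PBS, 6.24 to 54.2 CPM in carboplatin and 115 to 476 CPM in selumetinib. Peg10, an imprinted gene of the same list, was at 385 and 375 CPM in selumetinib 1 and 2 and at most 134 CPM elsewhere. Ppp1r1b, the striatal phosphoprotein DARPP-32, which the cortex and striatum list holds, was at 343, 352 and 419 CPM in carboplatin 1 to 3 and 27.8 to 89.7 CPM in the other 9 libraries. These genes were chosen after their values were seen.

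Some glucocorticoid response genes (5 of 7) and p53 targets (4 of 29) were high in carboplatin, and the tests below were run on the glucocorticoid list. Muscle, retina or neuronal RNA as the whole cause is argued against, since the glucocorticoid median stayed at 1.51 with these scores as covariates, against 2.43 before. Pigment cell genes, with a median of 5.49 in carboplatin against PBS, were not among the covariates, so their tissue stays open. Of the 5 glucocorticoid genes called only Tsc22d3 still passed. Fkbp5 went from 3.20 ± 0.37 to 2.61 ± 0.51 and Cdkn1a from 3.51 ± 0.49 to 4.27 ± 0.79, so their SE grew. For Sgk1 the fold was smaller, from 2.93 ± 0.46 to 1.51 ± 0.43. Sex as the whole cause is argued against by a median of 2.16 among only the libraries with Y-linked counts. Another hour of collection cannot be told apart: the clock scores of carboplatin and selumetinib differed by 0.0278, with PBS 1 to 3 above and PBS 4 to 6 below both, but Cry1 was at 28.8 CPM in carboplatin and 17.8 in selumetinib. Behind this pattern may stand a response to the drug or to the stress of treatment. That is a hypothesis, which these samples do not separate from the hour of collection, pigment cell RNA or handling of the groups.

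Neuronal genes were high in selumetinib 1 and 2. Hypothalamic tissue in these libraries is a candidate explanation: their hypothalamus score lay 4.04 above the mean of the other 10 libraries, against 1.83 for cortex, hippocampus and striatum, and 13 of 16 hypothalamus genes exceeded every other library in both (10 of 19 for the other list), with Pmch at 4.00 and 75.1 against a mean of 0.364 CPM, Agrp at 20.3 and 23.2 against 0.635 and Resp18 at 244 and 240 against 20.3. A lower share of oligodendrocyte RNA alone is argued against, since the microglia score lay at -0.823 and the endothelial score at -0.914 relative to the other libraries without PBS 1, while the neuron score lay at 2.36. An effect of selumetinib itself cannot be told apart, because selumetinib 3 is 1 library and does not decide it. Its neuron score lay 0.220 above the mean of all PBS libraries. That mean is lowered by PBS 1, whose neuron score lay at -1.38 relative to PBS 2 to 6, so the 0.220 shows no rise. The hypothalamus list was written after the neuronal genes were seen. The values of 7 of its 23 genes had been seen too, so these were left out of the test. So were 2 genes of the other list. With all genes kept, 16 of 23 hypothalamus genes and 10 of 21 of the other list exceeded every other library in both.

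Other splits of the same libraries were tested in the same way. For carboplatin against PBS 1 of 84 splits, the real one, gave as many as 383 genes, and the highest other gave 226. This share is under 0.05, so a random split of these libraries is argued against as the source of the count. It is also the smallest share that 84 splits allow. It does not set the drug apart from other differences between the groups, such as retina and pigment cell RNA. For the 19 lists called there at the preset correlation chance cannot be excluded, since 46 of 84 splits gave as many and the highest other gave 27. With fry the real split gave 8 lists, 2 of 84 splits gave as many, and the highest other also gave 8. For selumetinib against PBS the real split gave 0 genes, so each of the 84 of 84 splits gave as many and the count says nothing about chance (highest other 4684). For its 26 lists chance cannot be excluded (15 of 84, highest other 31). The split with 4684 genes set PBS 1, selumetinib 1 and selumetinib 2 against the other 6 libraries, which points to a structure of the samples other than the treatment. For carboplatin against selumetinib 10 splits are too few for a share under 0.05, with 2568 genes against a highest other of 68 (1 of 10 splits as large) and 19 lists against 23 (5 of 10), or 8 lists against 3 with fry (1 of 10). The same holds for PBS 1 to 3 against 4 to 6, with 1 gene against 0 (1 of 10).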
